A study of Caenorhabditis elegans with 12 samples.

How the data were processed

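Polyadenylated RNA was sequenced from 12 samples of Caenorhabditis elegans that carried fog-1(q253), a temperature-sensitive allele of a gene needed for sperm fate in the germline, so that at 25 °C the germlines of both XO and XX animals make oocytes in place of sperm. The samples formed 4 groups of 3 replicates: gonads dissected from XO and from XX young adults, and whole XO and XX young adults. Per the labels' protocols, each gonad sample held at least 200 gonads and each whole worm replicate at least 600 hand-picked animals, RNA was selected on oligo(dT) beads, and cDNA was made with dUTP so that libraries kept strand. The group and the replicate number of each sample came from its title. The labels did not say whether replicates came from separate cultures, so p-values here measure the spread between samples, which may be technical.

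The authors deposited 1 table of raw read counts per gene for each library, with no normalization. The submitters' processing notes name CASAVA 1.8, TopHat2 2.0.12, SAMtools 1.2, HTSeq and Cufflinks 2.2.0, without saying what each was used for. The genome build, the annotation release and the strand setting of the counting were not given in the sources used here, so reads of overlapping or antisense genes could not be told apart with certainty. The summary lines at the end of each file, which count reads with no gene, with several genes or with several places in the genome, were kept out of library sizes and tests. Reads with several places made up 7.15% ± 1.43 (SD, n = 3) of XO gonad reads, 7.21% ± 1.96 of XX gonad reads, 13.5% ± 0.702 of XO whole worm reads and 19.3% ± 1.48 of XX whole worm reads. Because such reads were set aside, genes with near-identical copies, such as those for major sperm proteins, vitellogenins and histones, may be undercounted or may share reads.

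Each file held 20389 gene rows under sequence names. Of these, 19899 matched 1 gene of the WBcel235 annotation, which gave symbols, chromosomes and exonic lengths, and 490 did not match and were kept without a chromosome. Coordinates are not printed, since the build behind the counts was not named. Libraries held from 7912618 to 16140259 gene counts. Intervals on ratios and floors cover counting error only, and amplified reads without molecular identifiers are not independent molecules.

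Tests used edgeR 4.0.16 in R 4.3.3 on the deposited counts, with the trimmed mean of M-values (TMM) for scaling, filterByExpr with a minimum count of 10, robust quasi-likelihood fits, 2-sided tests and Benjamini-Hochberg adjustment at 0.05. The XO against XX comparisons were fitted within each tissue on its 6 libraries. The interaction of karyotype and tissue, and the comparisons of gonad with whole worm, were fitted on all 12 libraries, which then shared an estimate of spread. Standard errors (SE) of log2 fold changes were taken from the F statistic. Levels are CPM, read counts scaled by TMM and library size, given as mean ± SD over 3 libraries. Where a group had 0 counts, the fold is a bound against a floor of 3 counts over the group. Values with 1 library left out are fitted values without such a bound. They do not measure a fold where the remaining libraries of a group hold few or no counts. Where it had 1 to 3 counts, the ratio of CPM is given with its 95% counting interval.

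X-linked genes were compared with autosomal genes by the difference of their median log2 fold changes, by camera from limma 3.58.1, and, per library, by the difference of median log2 CPM with an exact 2-sided permutation test. Camera used a preset correlation of 0.01 and, as a stricter alternative, an estimated correlation. Gene lists were written before the data were examined, as were the tests, the samples in each fit and the rule for named genes. They covered vitellogenins, oocyte, major sperm protein, other spermatogenesis, meiotic, germline stem cell, P granule and small RNA, sex determination, dosage compensation, chromatin, apoptosis and male somatic genes. The others were hermaphrodite somatic gonad and vulva genes, markers of intestine, muscle, cuticle, neurons, coelomocytes and pharyngeal glands, and heat shock, mitochondrial, histone and ribosomal protein genes. The symbols rad-54, cde-1, opt-2, unc-17, cha-1 and daf-21 were not matched in those lists, though daf-21 is an older name of hsp-90, which was a member. Set tests needed at least 3 tested members and were adjusted over the lists of a comparison.

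The named genes were the 10 largest changes per direction for XO against XX in each tissue, 5 for the interaction and 3 for each tissue comparison. They had to pass the test, differ at least 2-fold, have replicate values that did not overlap (for XO against XX and for tissues), and reach a mean of 10 CPM. Up to 4 members of each list with the smallest adjusted p and a mean of at least 1 CPM could be named too, and fog-1, her-1, xol-1, fog-3, tra-2 and fem-3 were always included. Genes named outside this rule are members of a fixed list that passed the test, or, in the closing section, members of a list written after the data were seen, whether or not they passed.

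Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter and a filter of 5 CPM in 3 libraries, a 2-fold threshold, the replicate number as a block, all 12 libraries in each fit, library sizes without the 20 most abundant genes, and each library left out in turn. A fit with the trend on exonic length removed, TMM from autosomal genes, and a restriction to genes at least as abundant in XX gonads as in XX whole worms were chosen after seeing the data. The fits were tested on simulated counts with 200 changed genes. At 2-fold, 34.3% of changed genes were called in the gonad simulation, 92.5% in the whole worm simulation and 23.9% in the interaction simulation, and at 4-fold 78.8%, 100% and 81.8%. Of all calls, 8 of 83, 16 of 189 and 6 of 77 were genes that had not been changed. An X-to-autosome difference of -1 put into the simulations was recovered as -1 in gonads and -0.99 in whole worms. Figures were drawn with matplotlib 3.10.9.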

Results

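The series measured gene expression in feminized germlines of XO and XX animals, and in the whole animals that carry them. Sex in C. elegans follows the number of X chromosomes: XX animals have a hermaphrodite (here female) body and XO animals a male body. In fog-1 mutants at 25 °C both make oocytes, so their germ cells share a fate but differ in X number and in the sex of the body around them. The dissected gonads also held somatic gonad cells, whose sex differs between XO and XX. Differences between XO and XX gonads are therefore not of germ cells alone. Each of the 4 groups had 3 libraries. The libraries of XO gonads held 13397775, 16140259 and 14328309 gene counts and those of XX gonads 13200850, 16026824 and 11911364. The libraries of XO whole worms held 7912618, 11815117 and 14051532 gene counts and those of XX whole worms 12765678, 13261934 and 15363288.

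Replicates of a group differed by more than sampling noise in every pair, so no library was a copy of another. The chi-square of counts per degree of freedom between replicates ran from 4.8 to 19.7 in every pair without XX gonad replicate 1. That library stood apart from XX gonad replicates 2 and 3, the larger value being 155, while those 2 differed from each other by 17.9. Its deviation from the other XX gonads fell with the exonic length of the gene (Spearman's rho across genes -0.49, genes not being independent replicates). Genes over 4 kb had a median log2 deviation of -1.34 and genes under 1 kb one of 0.26. Within the fixed lists, the median log2 deviation of XX gonad replicate 1 was -2.64 for dosage compensation genes, -0.85 for chromatin regulators and -0.79 for germline stem cell genes. It was -0.47 for meiotic genes, -0.32 for P granule and small RNA genes, 0.65 for intestine markers and 0.44 for ribosomal protein genes. With a trend on exonic length removed, these medians were, in the same order, -1.8, -0.59, -0.22, -0.29, 0.07, 0.58 and 0.18.

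**Figure D1:**
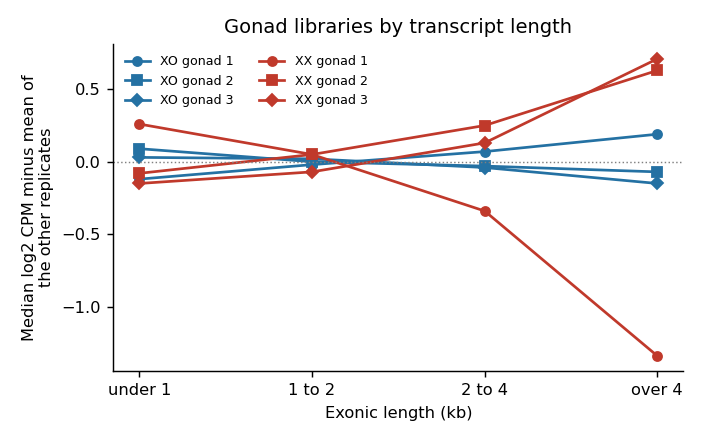
Median log2 CPM of each gonad library minus the mean of its other replicates (y axis), by exonic length of the gene in kb (x axis), for XO (blue) and XX (red) gonads, with symbols for the replicate number. XX gonad replicate 1 falls to -1.34 for genes over 4 kb, where XX gonad replicates 2 and 3 lie at 0.63 and 0.71. The values of replicates 2 and 3 are not independent of replicate 1, which is part of the mean subtracted from each.

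The mutated gene was examined first. Transcripts of fog-1, which encodes an RNA-binding protein that sets sperm fate, were at 612 ± 11.9 CPM in XO gonads and 42.8 ± 4.69 in XX gonads, and at 303 ± 9.4 in XO and 30.4 ± 1.5 in XX whole worms (n = 3 each). The log2 fold changes of XO over XX were 3.84 (SE 0.12) and 3.32 (SE 0.06), with adjusted p = 2.74e-05 and 6.84e-14 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. All libraries carry the same allele, which is a point change and not a deletion, so this level does not check the genotype. It does separate the XO from the XX libraries in both tissues.

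In gonads, X-linked genes were lower in XO than in XX animals. Of 955 X-linked genes tested, 777 (81.4%) fell and 53 rose, with a median log2 fold change of -2.90 (interquartile range -3.72 to -1.96), against 0.08 for 7480 autosomal genes. The difference of medians was -2.98, a 7.88-fold lower level. X-linked genes took 0.485% ± 0.0264 of counts in XO gonads and 2.61% ± 0.195 in XX gonads (n = 3). A per-library measure used the genes tested in the fit of all 12 libraries, with 1763 X-linked genes in place of 955. The median log2 CPM of X-linked genes minus that of autosomal genes was -4.24, -4.09 and -4.23 in XO gonads and -2.88, -3.01 and -2.98 in XX gonads. The mean difference was -1.23, smaller in size than the -2.98 above, from which it differs in genes and measure. For this measure and for the share of counts the exact 2-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. Camera gave p = 4.57e-75 with the preset and p = 0.00099 with an estimated correlation.

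**Figure D2:**
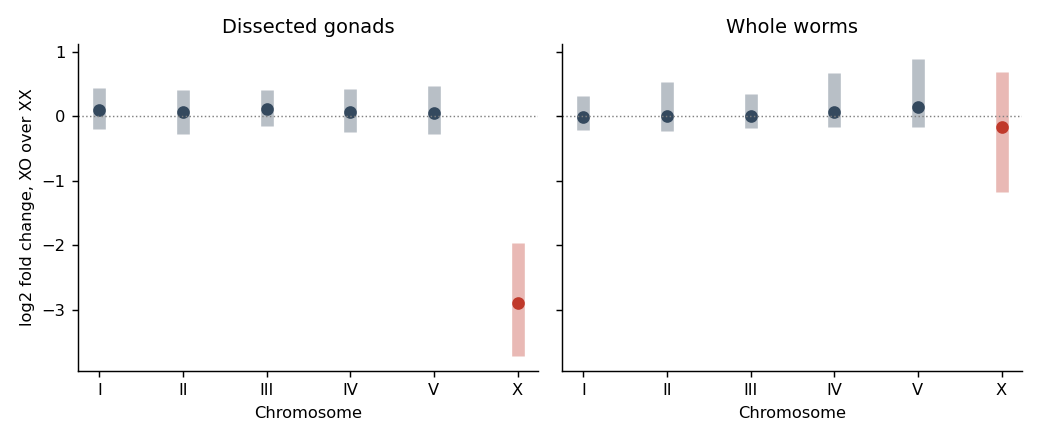
Median log2 fold change of XO over XX (points) and interquartile range (bars) of the genes tested on each chromosome, in dissected gonads (left) and whole worms (right). In gonads the autosomes have medians from 0.05 to 0.11 and the X chromosome -2.90; in whole worms the X chromosome has a median of -0.16.

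The strongest X-linked falls in gonads included tbh-1, which encodes the enzyme that makes octopamine, at 0.428 ± 0.214 CPM in XO and 169 ± 5.16 in XX gonads (log2 fold change -8.59, SE 0.34). The others among the 10 largest falls were C17G1.2 (-7.79), C39D10.7 (-7.64), the protease-like gene try-14 (-7.60) and T04G9.7 (-7.40). Autosomal genes among the 10 largest falls were C44B7.5 (-8.11), cht-3 (-7.37), a chitinase-like gene, skpo-1 (-7.35), a peroxidase gene, perm-4 (-7.02), needed for the eggshell's permeability barrier, and T01D1.4 (-7). Without XO gonad replicate 2 the values were -9.56 for C44B7.5, -9.24 for C17G1.2, -8.62 for C39D10.7, -8.44 for try-14, -7.81 for perm-4 and -7.86 for T01D1.4.

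The 10 largest rises in XO gonads were all autosomal. They included the trypsin-like protease genes try-13, at 50.3 ± 12 CPM against 0.127 ± 0.22 (log2 fold change 8.58, SE 0.74), and try-8, at 37.1 ± 13.2 against 0.225 ± 0.136 (7.33, SE 0.46). F26D2.16 rose by 7.94, K12H6.4 by 7.07, F26D10.13 by 7.07 and K11D12.6 by 7.04 on the log2 scale. K12H6.9 had 2 counts over the XX gonads, a ratio of 518 (interval 143 to 4280), C16C8.9 had 1 (ratio 506, 90.4 to 20000), M176.10 had 2 (ratio 256, 70.5 to 2120) and F54D12.9 had 2 (ratio 244, 67.1 to 2020). With XX gonad replicate 1 left out, few or no counts remained in XX gonads for try-13, K12H6.9, C16C8.9, F54D12.9 and F26D10.13. Their fitted values of 12.50, 11.51, 10.47, 10.43 and 10.99 then have no bound and do not measure a fold. The log2 fold change without that library was 7.94 for try-8, 8.35 for K12H6.4 and 8.32 for K11D12.6. Without XX gonad replicate 2 it was 7.92 for try-13, 8.15 for K12H6.9, 7.07 for F54D12.9, 6.42 for K12H6.4, 6.41 for F26D10.13 and 6.39 for K11D12.6.

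In all, 2376 of 8558 genes passed edgeR's quasi-likelihood test at an adjusted p of 0.05 in gonads, 691 higher and 1685 lower in XO, of which 1521 (629 higher and 892 lower) were autosomal. A difference of at least 2-fold was met by 1803. The common biological coefficient of variation was 0.269, and 0.12 without XX gonad replicate 1, when 3785 genes passed. Higher calls were the more sensitive: 376 without XO gonad replicate 3, 401 without XO gonad replicate 2, 412 without XO gonad replicate 1, 422 without XX gonad replicate 2, and 1667 without XX gonad replicate 1.

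Among the sex determination genes in gonads, 5 rose, 3 fell and 9 did not pass; adjusted over the list alone, 6 rose and 4 fell. fog-3, which acts with fog-1 in sperm fate, rose by 4.01 (60.1 ± 1.29 against 3.7 ± 0.502 CPM). mab-3, a male-promoting transcription factor gene, rose by 4.55, and her-1, which encodes the secreted signal for male fate, rose by 2.91 (9.52 ± 2.02 against 1.25 ± 0.245 CPM). fem-3, which promotes male fate, rose by 0.48, a call lost without any 1 of the XO gonad libraries or XX gonad replicate 2 (adjusted p 0.102, 0.079, 0.109 and 0.052 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). tra-2, which encodes the receptor that HER-1 binds, had a log2 fold change of 0.15 (SE 0.34), and the X-counting switch xol-1 one of -1.51 (SE 0.57); neither passed. With XX gonad replicate 1 left out, xol-1 did pass (-1.91), and tra-2 was at -0.14. The X-linked RNA-binding protein gene fox-1, an X-signal element, fell by 4.21. The 2 tested male somatic genes, mab-3 and her-1, both rose, also when adjusted over the list alone.

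Oocyte genes differed little. Of 32 tested, 29 did not pass, none rose and 3 fell, also when adjusted over the list alone: perm-2 (-6.59) and perm-4 (-7.02), both for the eggshell, and the X-linked meg-1 (-2.72), needed for germ cell development. The list median was -0.19, with adjusted p = 0.188 by camera and adjusted p = 0.0102 by fry. Without XX gonad replicate 1, or without XX gonad replicate 3, 7 members passed. None of the 30 major sperm protein genes had enough counts to be tested, and none of the 5 other spermatogenesis genes tested passed (median 0.25, camera adjusted p = 0.437), while 2 passed without XX gonad replicate 1. The 6 vitellogenins, yolk protein genes of the intestine with near-identical copies whose reads may be shared, all fell, also when adjusted over the list alone (median -3.08). vit-2 went from 155 ± 15.1 CPM in XX to 18.4 ± 9.58 in XO gonads. For this list camera's adjusted p = 0.00235, and adjusted p = 0.626 with an estimated correlation.

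Meiotic genes had a median of 0.38 in gonads. Of 36 tested, 7 rose and 29 did not pass, and 1 rose when adjusted over the list alone. They included the axis gene htp-3 (0.45, SE 0.08), him-5 (0.55), needed for breaks on the X chromosome, and the cohesin genes coh-3 (0.68) and rec-8 (0.50). As a set they passed camera at adjusted p = 0.00401, and had adjusted p = 0.626 with an estimated correlation. By fry the set had adjusted p = 0.0826. The call of him-5 was lost without XO gonad replicate 2 or 3 or XX gonad replicate 3 (0.49 to 0.54). That of coh-3 was lost without any 1 XO gonad library or XX gonad replicate 2 (0.63 to 0.73), and that of rec-8 without any 1 XO gonad library or XX gonad replicate 3 (0.48 to 0.53). The number of passing members depended on single libraries: 18 without XX gonad replicate 1, 3 without XX gonad replicate 2 or without replicate 3, 2 without XO gonad replicate 1, and 1 without XO gonad replicate 2 or without replicate 3. In this list XX gonad replicate 1 had a median deviation of -0.47, and of -0.29 with a length trend removed.

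P granule and small RNA genes had a median of 0.27. 1 of 26 rose, ekl-1 (0.43), and none when adjusted over the list alone. The list passed camera at adjusted p = 0.0298, with adjusted p = 0.0512 without XO gonad replicate 1, and adjusted p = 0.626 with an estimated correlation. By fry it had adjusted p = 0.135. XX gonad replicate 1 had a median deviation of -0.32 in this list, and of 0.07 with a length trend removed. The ekl-1 call was lost without any 1 library other than XX gonad replicate 1 (0.41 to 0.49), and without that library 10 members passed. Of 14 germline stem cell genes, fbf-1, which encodes a repressor of meiotic entry, rose by 0.51, lst-1, a Notch target, fell by 0.39 and 12 did not pass (median 0.35; the same counts adjusted over the list alone). Both calls were lost without XO gonad replicate 1 (0.44 and -0.38) or without XO gonad replicate 2 (0.50 and -0.43), fbf-1 also without XX gonad replicate 3 (0.47), and lst-1 also without XO gonad replicate 3 or XX gonad replicate 2 (both -0.41).

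Of 10 dosage compensation genes, the X-linked sdc-1 fell by 1.51, dpy-30 fell by 0.43 and 8 did not pass; none passed adjusted over the list alone. The median was 0.17 and the mean -0.19, with camera's direction upward (adjusted p = 0.556). XX gonad replicate 1 had a median deviation of -2.64 in this list, and 5 members passed without it, against 0 without XO gonad replicate 1, XO gonad replicate 2 or XX gonad replicate 2 and 1 without XO gonad replicate 3 or XX gonad replicate 3. The sdc-1 value was then between -1.60 and -1.31 and that of dpy-30 between -0.47 and -0.43. With a length trend removed, the median deviation of XX gonad replicate 1 in this list was -1.8. Of 18 chromatin regulators, the X-linked hpl-1 (-5.04), a heterochromatin protein gene, and utx-1 (-2.18), a histone demethylase gene, fell, also when adjusted over the list alone, and 16 did not pass (median 0.30, mean -0.18; camera upward, adjusted p = 0.556). Without XX gonad replicate 1, 7 passed. None of 11 apoptosis genes passed by edgeR's quasi-likelihood test (median 0.17), while 1 passed without XX gonad replicate 3.

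Markers of other tissues moved in both directions in gonads. Hermaphrodite somatic gonad and vulva genes had a median of -2.07: 4 of 9 fell (5 adjusted over the list alone), including the sheath gap junction gene inx-8, at 1.52 ± 0.394 CPM in XO and 100 ± 13.6 in XX (-6.03), and lim-7 (-3.52), a sheath transcription factor gene. The set had camera's adjusted p = 0.0679 and fry's adjusted p = 0.00184, and 7 members passed without XX gonad replicate 1. 7 of 15 muscle markers fell (median -1.29; adjusted over the list alone 8 fell and 1 rose), of which 4 are X-linked, including unc-27 (-1.90) and tni-1 (-3.33), both troponin I genes, and 3 are autosomal: unc-15, pat-10 and myo-3. The set passed camera at adjusted p = 0.0265, and adjusted p = 0.588 with an estimated correlation.

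Intestine markers rose in 5 of 7 cases (6 adjusted over the list alone, median 1.2), for example the protease gene asp-1 at 109 ± 18.6 CPM in XO and 28.6 ± 8.72 in XX gonads (1.92), with camera's adjusted p = 0.00298, and adjusted p = 0.588 with an estimated correlation. 3 passed without XO gonad replicate 2 or without XX gonad replicate 2. Of 6 cuticle markers, 4 rose (5 adjusted over the list alone, median 1.01; camera, adjusted p = 0.0503), among them the collagen genes sqt-3 (1.74) and col-119 (1.03), with 1 or 2 passing without any 1 XO gonad library or without XX gonad replicate 2, when col-119 lay between 0.98 and 1.05. By fry the cuticle list had adjusted p = 0.0132. In XX gonad replicate 1 the intestine and cuticle lists had median deviations of 0.65 and 0.45, and of 0.58 and 0.38 with a length trend removed. The neuron markers unc-31 (1.45) and ida-1 (2.35) rose, unc-119 (-1.25) fell and 6 of 9 did not pass, also when adjusted over the list alone; ida-1 was 3.16 without XX gonad replicate 1 and lost its call without XO gonad replicate 2 or 3 or XX gonad replicate 2 or 3 (1.98 to 2.37), and unc-31 without XO gonad replicate 1 (1.33). No coelomocyte or gland marker had enough counts to be tested.

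Of 25 histone genes, whose copies are near-identical so that reads may be shared, 6 rose, such as his-32 (1.93), 4 fell, such as the X-linked his-71 (-2.12), and 15 did not pass (adjusted over the list alone 8 rose and 4 fell; median 0.36). Without any 1 library other than XX gonad replicate 1, between 4 and 6 passed. Among ribosomal protein genes 72 of 74 did not pass, and the X-linked rpl-11.2 (-2.27) and rpl-23A.1 (-1.29) fell (median -0.14; the same counts adjusted over the list alone). Of 9 heat shock and stress genes the X-linked hsp-3, an endoplasmic reticulum chaperone gene, fell by 2.71 and 8 did not pass (the same adjusted over the list alone), with 3 passing without XX gonad replicate 1. None of 7 mitochondrially encoded genes passed by edgeR's quasi-likelihood test (median 0.02).

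**Figure D3:**
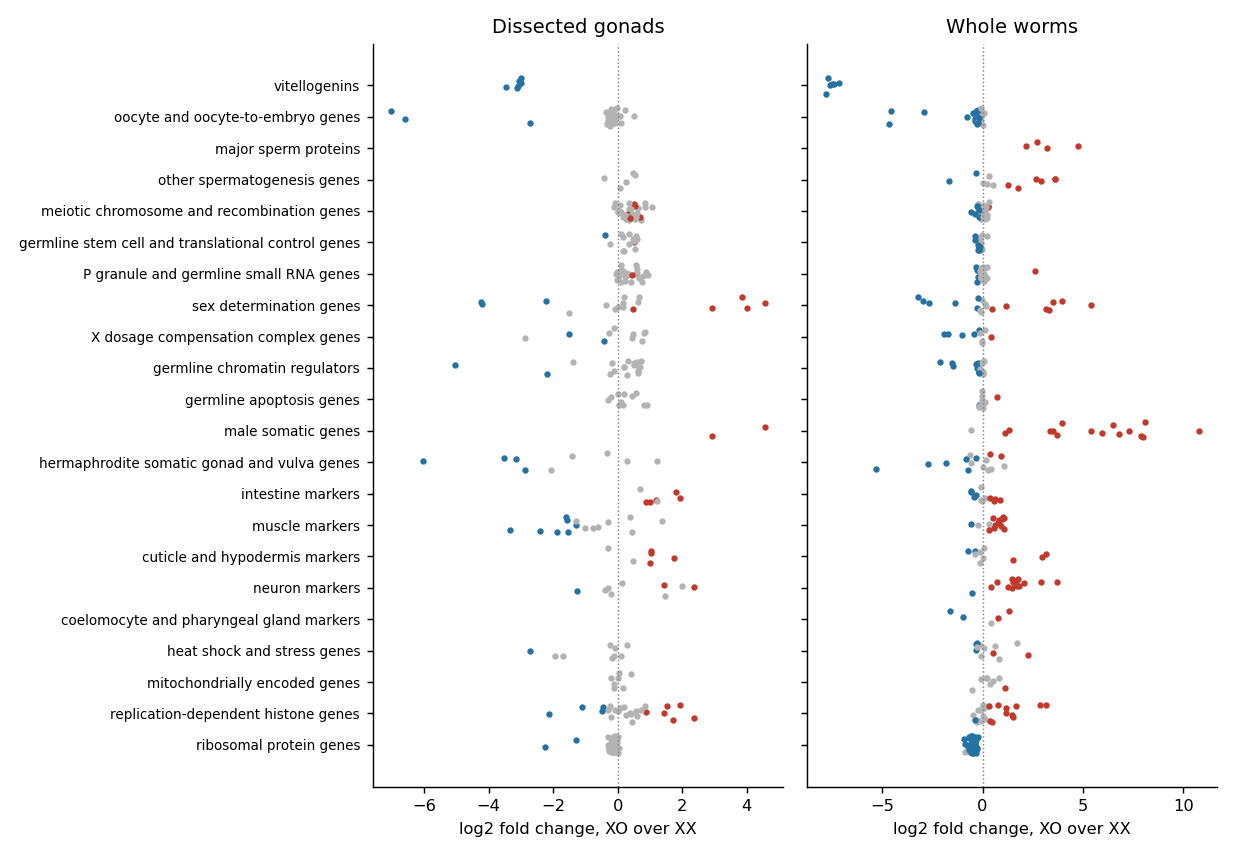
Log2 fold change of XO over XX for every tested member of the fixed gene lists (points), in gonads (left) and whole worms (right); red points are higher and blue points lower past an adjusted p of 0.05, and grey points did not pass. The vitellogenins have a median of -3.08 in gonads and -7.54 in whole worms, and the male somatic genes one of 5.69 in whole worms.

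Whole worms addressed the same contrast with the male or female body included. The largest rises in XO worms were genes with 0 counts in the XX libraries. They were scl-9, which encodes a secreted SCP-like protein, at 70 ± 6.61 CPM in XO worms and at least 889-fold higher, the C-type lectin genes clec-133 (at least 677-fold) and clec-217 (at least 634-fold), D1022.2 (at least 661-fold), F42A6.2 (at least 652-fold), R11G10.4 (at least 612-fold), Y49F6B.6 (at least 595-fold), K03B8.14 (at least 531-fold), W09G12.6 (at least 515-fold) and F56D2.8 (at least 506-fold). The largest falls were Y48E1B.8, with 1 count over the XO libraries and a ratio of 1060 (interval 191 to 42100; fitted at -11.48 without XO whole worm replicate 2), vit-5 (-7.81), D1086.7 (-7.68), vit-3 (-7.67), vit-4 (-7.59), ule-1 (-7.56), vit-6 (-7.49), ZK813.2 (-7.45), ule-2 (-7.44) and C44B7.5 (-7.40). The ule genes are named for expression in the uterine lumen. In XO worms the levels of the vitellogenins varied as much as their mean, as for vit-5 at 77.7 ± 89 CPM against 17100 ± 1570 in XX worms. Without XO whole worm replicate 1 the log2 fold changes were -9.29 for vit-5, -9.04 for vit-3, -9.12 for vit-4, -8.91 for vit-6, -8.37 for ule-1, -9.02 for ule-2, -8.26 for ZK813.2 and -8.30 for C44B7.5. Without XO whole worm replicate 2 they were -7.08 for D1086.7, -6.84 for ZK813.2 and -6.83 for ule-2. The vit-6 call was lost without XO whole worm replicate 3 (-7.26).

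In whole worms 6546 of 12259 genes passed edgeR's quasi-likelihood test at an adjusted p of 0.05, 3584 higher and 2962 lower in XO, and 3077 also differed at least 2-fold (2020 higher, 1057 lower). The biological coefficient of variation was 0.0845. In a fit of all 12 libraries, where the spread, the scaling and the filter were shared with the gonads, 5032 genes passed and the share of lower calls was 33.4%, against 45.2% here.

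Male somatic genes rose in 15 of 16 cases, with a median of 5.69 (4.69 with genes at 0 in a group set to their bound; adjusted over the list alone, 15 rose and 1 fell). mab-3 rose by 5.41 (67.8 ± 5.35 against 1.58 ± 0.485 CPM) and pkd-2, a polycystin gene of male sensory neurons, by 8 on the log2 scale. cwp-1 and cwp-2, expressed with the polycystins, had 3 counts each over the XX libraries and ratios of 299 (102 to 1450) and 267 (91.2 to 1300). Without XX whole worm replicate 1 pkd-2 was at 9.24, and without XX whole worm replicate 3 cwp-1 was at 8.81 and cwp-2 at 8.64. The set passed camera at adjusted p = 1.25e-13, and adjusted p = 0.0994 with an estimated correlation.

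Of 18 sex determination genes 7 rose, 6 fell and 5 did not pass, also when adjusted over the list alone (median 0.03). her-1 rose by 3.50, fog-3 by 3.17 and fem-3 by 0.46. tra-2 fell by 0.27, the X-linked nuclear receptor gene sex-1, an X-signal element, by 2.94 and xol-1 by 1.37, or to -2.10 without XO whole worm replicate 2.

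Neuron markers rose in 15 of 16 cases and unc-119 fell, also when adjusted over the list alone (median 1.54). The vesicle genes rab-3 (3.70) and snt-1 (2.90) and the neuropeptide convertase gene egl-3 (1.5) were among them. The set passed camera at adjusted p = 7.97e-06, and adjusted p = 0.285 with an estimated correlation. Of 15 muscle markers 12 rose, such as mlc-3 (1.05), a myosin light chain gene, and the paramyosin gene unc-15 (1.02), and tni-1 fell, with a median of 0.77 and the same counts adjusted over the list alone. Camera gave adjusted p = 0.0381, and adjusted p = 0.893 with an estimated correlation.

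Of 32 oocyte genes 22 fell and none rose (25 fell adjusted over the list alone, median -0.22), led by perm-2 (-4.68), perm-4 (-4.56), meg-1 (-2.93) and the chitin synthase gene chs-1 (-0.76). The set passed camera at adjusted p = 8.68e-06, and adjusted p = 0.629 with an estimated correlation. Of 36 meiotic genes htp-3 (0.28) and coh-3 rose, 6 fell, such as zyg-12 (-0.60) and sun-1 (-0.29), which link nuclei to the cytoskeleton, and 28 did not pass (median 0.02, mean -0.01). Adjusted over the list alone, 1 rose and 2 fell, against the 8 over all genes tested. Of those over all genes, 3 passed without XX whole worm replicate 1, 4 without XX whole worm replicate 2 or XO whole worm replicate 2, and 5 without XX whole worm replicate 3. The htp-3 call was lost without XX whole worm replicate 1 (0.23) or 2 (0.22). Of 14 germline stem cell genes 7 fell, such as gld-4 (-0.39), a poly(A) polymerase gene, and lst-1 (-0.37), and none rose (8 fell adjusted over the list alone, median -0.15). Of 27 P granule and small RNA genes 5 fell, such as pgl-3 (-0.26) and glh-1 (-0.27), and alg-3, an Argonaute gene of spermatogenesis, rose by 2.64, or by 3.31 without XX whole worm replicate 3, with 21 not passing (median 0.02, mean 0.07, camera downward with adjusted p = 0.779; the same counts adjusted over the list alone).

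Of 10 dosage compensation genes 5 fell, such as sdc-1 (-1.92), sdc-2 (-1.73) and sdc-3 (-1.01), and dpy-21 rose (median -0.14; the same counts adjusted over the list alone). Of 18 chromatin regulators 10 fell and none rose, with the same counts adjusted over the list alone. The falls were led by the X-linked utx-1 (-2.14), hpl-1 (-1.54) and lin-15B (-1.45). The list median was -0.18, with adjusted p = 0.0834 by camera and adjusted p = 0.000888 by fry. Of 11 apoptosis genes ced-3, a caspase gene, fell by 0.17, egl-1, its upstream activator, rose by 0.74 and 9 did not pass, with none passing adjusted over the list alone (median -0.03, mean 0.03); the egl-1 call was lost without XO whole worm replicate 1 or 2 or XX whole worm replicate 2 or 3 (0.64 to 0.69).

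The 6 vitellogenins all fell, also when adjusted over the list alone (median -7.54). The set had adjusted p = 0.122 by camera and adjusted p = 0.001 by fry. 4 of 4 major sperm protein genes tested rose, also when adjusted over the list alone (median 2.97), at low levels: msp-59, whose reads may be shared with other copies, was at 1.11 ± 0.22 CPM in XO and 0.153 ± 0.0627 in XX worms (2.73). Without XO whole worm replicate 2, XX whole worm replicate 1 or XX whole worm replicate 3, 7 or 8 passed. Of 12 other spermatogenesis genes 6 rose, such as spch-1 (2.89), a sperm chromatin gene, and gsp-4 (3.59), a sperm phosphatase gene, and spe-44 and ssp-10 fell (median 0.89; the same counts adjusted over the list alone).

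Ribosomal protein genes fell in 72 of 74 cases (74 adjusted over the list alone), with a median of -0.47, a minimum of -0.95 and a maximum of -0.24, for example rps-11 at 1030 ± 130 against 1510 ± 48.6 CPM (-0.56). Camera gave adjusted p = 1.08e-05, and adjusted p = 0.893 with an estimated correlation. Of 25 histone genes, whose reads may be shared, 11 rose, such as his-32 (2.87), and his-74 fell by 0.36 (median 0.25; the same counts adjusted over the list alone).

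Of 15 hermaphrodite somatic gonad and vulva genes 6 fell, such as inx-8 (-5.31), fkh-6 (-2.73) and lim-7 (-1.83), and inx-9 (0.90) and fln-1 rose (median -0.31; adjusted over the list alone, 6 fell and 3 rose). Of 12 intestine markers 4 fell, such as cpr-6 (-0.58) and vha-6 (-0.32), and 4 rose, such as elt-7 (0.87), an intestinal GATA factor gene (median -0.06, mean 0.04, camera downward with adjusted p = 0.827; the same counts adjusted over the list alone), with 5 passing without XO whole worm replicate 2. Of 10 cuticle markers 3 rose, such as dpy-13 (2.94, or 4.73 without XX whole worm replicate 3), and col-19 (-0.40, with its call lost without XO whole worm replicate 2, at -0.33) and nlp-29 (-0.72) fell (median -0.05, mean 0.60, camera downward with adjusted p = 0.855; the same counts adjusted over the list alone), with 3 passing and the dpy-2 call lost (1.12) without XO whole worm replicate 3. Of 5 coelomocyte and gland markers phat-4 (-1.62) and phat-3 (-0.96) fell and unc-122 (1.31) and lgc-26 (0.79) rose (median 0.40, mean -0.02; the same counts adjusted over the list alone). Of 12 heat shock and stress genes hsp-4 (0.51) and F44E5.5 (2.25, or 1.66 without XO whole worm replicate 2) rose and hsp-60 (-0.32), hsp-1 (-0.34) and hsp-90 fell (median -0.01, mean 0.37; the same counts adjusted over the list alone), and 10 passed without XO whole worm replicate 1. 1 of 8 mitochondrially encoded genes, MTCE.34 (1.12), rose, a call lost adjusted over the list alone and without any 1 XX library (1.05 to 1.19; list median 0.32).

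X-linked genes in whole worms moved in both directions. Of 1716 tested, 723 fell and 512 rose, with a median of -0.16 (interquartile range -1.18 to 0.69) against 0.03 for 10372 autosomal genes, a difference of -0.19. Camera gave p = 7.55e-06, and p = 0.0392 with an estimated correlation. The difference was -0.07 without a filter on low counts, -0.33 with a filter of 5 CPM, -0.67 with means in place of medians and -1.73 among genes at least as abundant in XX gonads as in XX worms. X-linked genes took 6.5% ± 0.118 of counts in XO and 13.1% ± 0.779 in XX worms. Vitellogenins, of which 5 of 6 are X-linked, took 11.2% ± 1.3 of counts in XX and 0.0759% ± 0.0865 in XO worms. The other X-linked genes took 6.45% ± 0.0765 of all counts in XO and 6.31% ± 0.0744 in XX worms. That total still includes the vitellogenins, which lowers the XX value, so the 2 shares do not show equal X-linked output. Over the genes tested in the fit of all 12 libraries, the median log2 CPM of X-linked genes minus that of autosomal genes was -1.91 ± 0.0249 in XO and -1.27 ± 0.0344 in XX worms (n = 3). The difference of -0.643 is another measure than the -0.19 above. Its exact 2-sided permutation test gave p = 0.1, the smallest possible.

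**Figure D4:**
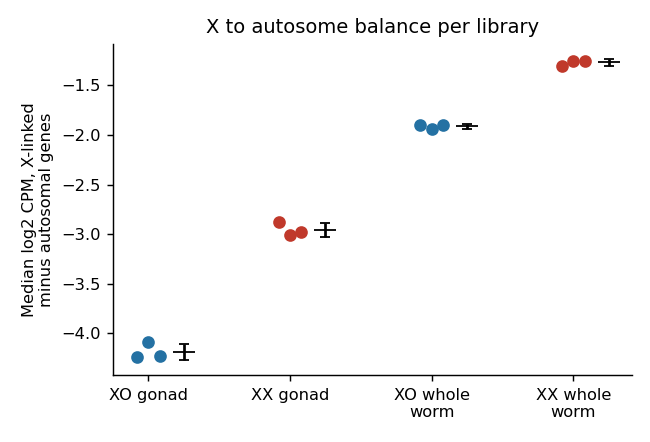
Median log2 CPM of X-linked genes minus that of autosomal genes in each library (points, blue XO, red XX), with the mean and SD of each group (black). The genes are those tested in the fit of all 12 libraries. XO gonads lie between -4.24 and -4.09 and XX gonads between -3.01 and -2.88, and XO whole worms between -1.94 and -1.90 against -1.31 to -1.25 in XX.

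Whether the XO against XX difference itself differed between gonads and whole worms was tested as an interaction. X-linked genes had a lower XO over XX ratio in gonads than in worms, with a difference from autosomal genes of -1.54 (camera, p = 1.2e-22, p = 0.000339 with an estimated correlation). By edgeR's quasi-likelihood test 2132 of 12528 genes passed an adjusted p of 0.05, with 371 ratios higher and 1761 lower in gonads, and 1828 also differed at least 2-fold. Of the 2132, 1657 (259 higher and 1398 lower) had enough counts to be tested in each tissue, and for the other 475 the ratio in at least 1 tissue is poorly determined.

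The largest interaction terms belonged to genes of the body that were near 0 in both kinds of gonad, so they follow the whole worm contrast and have no bound. T12B5.15 (9.89), C10G8.4 (8.65), Y48E1B.8 (7.33), spex-3 (6.52) and Y51H7C.1 (6.51) were high in XX worms, as for spex-3 at 124 ± 4.19 CPM against 6.62 ± 2.01 in XO worms and 0.0256 ± 0.0443 in XX gonads. F49F1.9 (-13.81), D1022.2 (-11.72) and the C-type lectin genes clec-181 (-12.01), clec-217 (-11.88) and clec-208 (-11.60) were high in XO worms, as for clec-208 at 85.5 ± 3.47 CPM against 0.0266 ± 0.0461 in XX worms. These genes had mean levels of at most 0.347 CPM in either kind of gonad. Without XX gonad replicate 1 the values were -8.85 for clec-181, -8.72 for clec-217, -9.07 for D1022.2 and -7.31 for clec-208, each with an adjusted p of 1 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and spex-3 was at 8.38. Without XX gonad replicate 1 Y48E1B.8 was at 8.53 and Y51H7C.1 at 7.33, without XX gonad replicate 3 C10G8.4 was at 10.53, without XO gonad replicate 3 D1022.2 was at -15.09, and without XX whole worm replicate 1 clec-208 was at -13.50. The calls of T12B5.15 (8.99 without XO gonad replicate 1) and C10G8.4 (7.22 without XO gonad replicate 2) were also lost. So were those of Y51H7C.1 (5.86 without XO gonad replicate 3 and 6.3 without XO gonad replicate 1) and Y48E1B.8 (6.74 without XO whole worm replicate 3, and lost without 5 others too).

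Among the lists, muscle markers had lower XO over XX ratios in gonads than in worms in 9 of 15 cases (median -1.94; camera, adjusted p = 2.75e-06, and adjusted p = 0.066 with an estimated correlation), and intestine markers higher ones in 6 of 12 (8 adjusted over the list alone; median 1.32; adjusted p = 0.000185, and adjusted p = 0.0588 with an estimated correlation). All 6 vitellogenins had higher ratios (median 4.31; adjusted p = 4.7e-05, and adjusted p = 0.5 with an estimated correlation). For meiotic, P granule and ribosomal protein genes camera also passed (medians 0.27, 0.26 and 0.23; adjusted p = 0.00305, 0.0167 and 0.000367), with adjusted p = 0.58, 0.58 and 0.752 with an estimated correlation, while 0, 0 and 1 of their members passed, the last being the X-linked rpl-11.2, which was lower, against the direction of its list. Cuticle markers passed with 2 of 10 members higher (5 adjusted over the list alone; median 0.59; adjusted p = 0.033, and adjusted p = 0.5 with an estimated correlation). By fry the meiotic, P granule and ribosomal protein genes had adjusted p = 0.21, 0.215 and 0.492. No other list passed camera. Fry passed for hermaphrodite somatic gonad and vulva genes (adjusted p = 0.00342), male somatic genes (0.00932), neuron markers (0.0122) and heat shock genes (0.000291). Lower ratios in gonads were called for 6 of 15 hermaphrodite somatic gonad and vulva genes, 4 of 16 neuron markers and 3 of 13 heat shock genes. So they were for 4 of 16 male somatic genes, of which only mab-3 had enough counts to be tested in gonads. The other lower ratios were of 3 of 29 histone genes, 3 of 18 sex determination genes, 2 of 32 oocyte genes and 1 of 18 chromatin regulators. Higher ratios were called for 2 sex determination genes, 1 histone gene and 1 of 14 other spermatogenesis genes, which was not tested in gonads. Of the called intestine, cuticle and hermaphrodite somatic gonad and vulva genes, 1 in each list lacked the counts for a test in gonads. None of the major sperm protein, germline stem cell, dosage compensation, apoptosis, coelomocyte and gland or mitochondrially encoded genes passed edgeR's quasi-likelihood test.

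The calls in gonads and in whole worms overlapped, from fits that shared no library. Whole worms include the gonads, so a shared call can come from the gonad in both and is not an independent recurrence. Of 8471 genes tested in both, 405 rose in both, against 120.7 for independent lists, and 1019 fell in both, against 482.1, so 1424 went the same way. Opposite calls were 25 higher in gonads and lower in worms, against 197.5, and 237 lower in gonads and higher in worms, against 294.7. For autosomal genes alone the shared calls were 363 higher, against 111.1, and 460 lower, against 218.6. Opposite autosomal calls were 17 higher in gonads and lower in worms, against 153, and 159 lower in gonads and higher in worms, against 158.6. Fisher's exact test of the shared calls over all genes gave p = 1.72e-146 for rises and p = 2.35e-211 for falls, adjusted over 12 such tests to 1.03e-145 and 2.82e-210. The test treats genes as independent, which they are not. Log2 fold changes had a Pearson correlation of 0.71 and a Spearman correlation of 0.48 across genes, which are not independent replicates.

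Gonads were also compared with whole worms of the same karyotype, which shows what the dissected tissue held. In XX animals 3575 genes were higher and 5318 lower in gonads (8893 of 12528), and in XO animals 3705 higher and 6297 lower (10002). The median over all genes was -0.32 in XX and -0.83 in XO, and -0.48 and -0.97 with the size factors of DESeq2, so directions are relative to the scaling. Y73B3A.1, an X-linked gene, was the gene most enriched in XX gonads, at 220 ± 39.1 against 42.6 ± 2.94 CPM (2.37), followed by Y10G11A.90 (1.78) and Y73B3A.4 (1.74). In XO animals H11L12.1 (1.86), glit-1 (1.61) and Y73B3A.1 (1.60), all X-linked, led. The largest falls in XX gonads were D1086.7 (at least 769-fold lower), spex-3 (1 count, ratio 5050, interval 905 to 199000) and ule-4 (2 counts, ratio 3870, 1070 to 31900), and in XO gonads abf-1 (at least 411-fold), an antibacterial factor gene, F49F1.9 (at least 322-fold) and clec-106 (at least 278-fold). Without XX gonad replicate 1, the fitted values were -13.69 for spex-3 and -14.30 for ule-4. With few or no counts left in XX gonads, these have no bound and do not measure a fold. X-linked genes lay below autosomal genes by a difference of medians of -1.92 in XX and -4.27 in XO (camera, p = 5.9e-10 and 2.22e-20, and p = 0.00867 and 0.0021 with an estimated correlation); with genes at 0 set to their bound these were -1.82 and -4.13.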

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

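The tests of oocyte genes, of 1 X copy, of low counts, of every other tissue and of exonic length, and the count of interaction calls among genes tested in both tissues, were chosen only after the results they concern were seen. A test of the difference between tissues in the XO over XX ratio was passed by 2132 genes, of which 1657 had enough counts to be tested in each tissue and 475 did not. X-linked genes had a lower ratio in gonads than in whole worms by -1.54 relative to autosomal genes, and by -1.94 among genes tested in each tissue. For the count of 2132, 1 of 100 splits, the real one, gave a result as large, and the highest of the others called 1365 genes. These splits exchange karyotype within a tissue and so also remove its effect there, so they decide nothing about chance for the interaction.

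X-linked genes were lower in XO gonads, by a difference of medians of -2.98. A lower content of cells that express the listed oocyte genes was argued against by the autosomal members, whose median was -0.18 (25th percentile -0.24). Of these 31 members 2 fell, perm-2 and perm-4. The list was not split by oocyte stage, so a difference in the maturity of oocytes stays open. Output in proportion to X copies (1 against 2) as the only cause was argued against by a 75th percentile of -2.04 relative to autosomal genes. Together with fewer somatic gonad cells, such output stays open, since both would lower X-linked genes. Low counts were argued against by a difference of -2.94 in the 239 X-linked genes with the highest levels. Fewer somatic gonad cells in XO gonads stay open: the 31 X-linked genes more enriched in XX gonads than the sheath gene inx-8 differed by -2.12 (75th percentile -0.67), and the other 924 by -3.01. For those 924 the first bound, a median below -2.90, was met by a median of -2.91, and after this was seen the 75th percentile (-2) was required instead, because inx-8 itself fell by 6.03; a difference in X-linked transcription between XO and XX germ cells is a candidate explanation that cannot be told apart from cell content here.

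Intestine and cuticle markers were higher and muscle and sheath markers lower in XO gonads. More of every other tissue carried along would, as the only cause, raise these lists alike. The autosomal intestine and muscle markers differed by 2.23 (medians 1.21 of 6 genes and -1.02 of 9, SDs 0.43 and 0.79). This gap is the pattern itself, so it is no separate test of that cause. Together with fewer somatic gonad cells in XO gonads, such carry-over stays open. Abundant body transcripts carried along with XO gonads may account for the rises: the 100 most abundant had a median of 0.74 (25th percentile 0.06), with 38 higher and 14 lower. These transcripts were not chosen by tissue, so they do not tell intestine and epidermis from other tissues of the body. The fall of muscle and sheath markers goes with the different somatic gonads of the sexes, which was not tested.

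XX gonad replicate 1 stood apart from the other XX gonads. Loss of long transcripts in that library may contribute, as its deviation correlated with exonic length at -0.49, but removing the trend lowered the chi-square per degree of freedom only from 147 to 95.1 and the coefficient of variation from 0.269 to 0.233. Another mix of cells stays open as well, with an SD over genes of 0.81 after the trend was removed, against at most 0.61 in the other XX gonads. The deviations of those other libraries are taken from a mean that includes replicate 1, so 0.61 is not independent of it. With 1 library, loss of long transcripts and another mix of cells cannot be told apart, and no biological explanation was tested.

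The interaction terms of T12B5.15 (9.89), C10G8.4 (8.65), Y48E1B.8 (7.33), spex-3 (6.52), Y51H7C.1 (6.51), F49F1.9 (-13.81), clec-181 (-12.01), clec-217 (-11.88), D1022.2 (-11.72) and clec-208 (-11.60) passed the same test. These genes had at most 0.347 CPM in either kind of gonad, so their XO over XX ratio in gonads is undetermined and a difference between tissues is not shown for them. Without XX gonad replicate 1, clec-181 was at -8.85, clec-217 at -8.72, D1022.2 at -9.07 and clec-208 at -7.31, each with an adjusted p of 1 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Reads with several places in the genome, which no comparison used, made up 19.3% ± 1.48 of reads in XX whole worms and 13.5% ± 0.702 in XO whole worms (exact permutation p = 0.1, the smallest possible).

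For the overlap of the 2 tissues, 1 of 100 splits gave a result as large as 1424, the highest of the others being 262. The other splits of either tissue called 0 genes and could share none, and 262 is the number of opposite calls in the real grouping, so these splits decide nothing about chance. The other comparisons have 10 splits, too few for a share under 0.05. Their real values and the highest of the other splits were 2376 and 0 genes in gonads, 6546 and 0 in whole worms, 8893 and 0 for XX and 10002 and 0 for XO gonads against worms. For the X-to-autosome difference in size they were 2.98 and 0.79 in gonads and 0.19 and 0.13 in worms. Gene lists past camera numbered 5 in gonads, with 9 as the highest other and 8 of the splits at least as large, and 5 in worms, with 9 as the highest other and 10 of the splits at least as large.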

How the results depend on the processing

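The fit with the length trend removed, TMM from autosomal genes and the restriction to gonad-abundant genes were chosen only after the data were seen. Over all alternatives, named genes kept direction and side of the threshold in 3142 of the values, were stronger in 50, reversed in 6 and weaker in the rest. Genes past the threshold in gonads (2376) were 1325 with the filter of 5 CPM (fewer genes tested) and 4046 with all 12 libraries in the fit. With 1 library left out they were 1741 to 3785, the highest without XX gonad replicate 1. In whole worms (6546) they were 3077 with a 2-fold threshold and 5830 to 6518 with 1 left out. Of the same calls, 872 in gonads and 2076 in whole worms were of gonad-abundant genes, which were not fitted or adjusted again. XX gonads against worms (8893) gave 5804 with the filter of 5 CPM, 5093 with a 2-fold threshold and 8391 to 9903 with 1 left out; XO gonads against worms (10002) gave 6125 and 9814 to 10191; the interaction gave 1801 to 2463. The X-to-autosome difference in worms (-0.19) was -0.07 without a filter, -0.33 with the filter of 5 CPM, -1.73 among gonad-abundant genes, -0.67 with means and -0.22 to -0.14 with 1 left out; the X minus autosome median log2 fold change, gonad XO vs XX, was -3.02 to -2.91. The overlap of gonad and whole worm XO vs XX calls (1424) was 799 with a 2-fold threshold and 1138 to 1871 with 1 left out. With DESeq2 the counts were 2634, 5826, 2379, 8306 and 9404 for gonads, worms, interaction, XX and XO tissues. Of the 2376 genes called in gonads, 3 changed sign with the length trend removed. Values of named genes that reversed, all without a call in gonads, were dpy-21 (-0.01) and tra-2 (-0.14) with the length trend removed, and with 1 library left out ND6 (-0.44 to 0.01), MTCE.34 (-0.05 to 0.82), MTCE.25 (-0.30 to 0.15) and tra-2 (-0.14 to 0.43). Except where fewer genes tested shows it, the cause was not tested. All 10 camera calls in the XO against XX comparisons were lost with an estimated correlation, and that of P granule genes in gonads also with the length trend removed (p = 0.167). With the replicate number as a block the counts were 1622, 6244, 1902, 8696 and 9887, but equal numbers correlated at most at 0 in worms and -0.12 in gonads, so the numbers do not pair samples. In the simulations 2-fold changes were called in 34.3% of cases in gonads and 92.5% in worms. The gonad simulation had 83 calls, against 2376 in the data, and the adjusted threshold loosens with more calls. The 34.3% need not be the share found in the data, and a missing gonad call does not show an unchanged gene.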

Other observations

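The gene families, named by symbol prefix, the early embryonic list and the rule for reading soma-enriched X-linked genes in whole worms were chosen or changed only after the data were seen. Nuclear receptor genes (nhr) were lower in XO gonads in 37 of 65 cases, against 12.8 for calls spread evenly (median -1.39), and 10 of the 65 are X-linked. Of the F-box families, 12 of 14 fbxb genes were lower (median -2.42), none of them X-linked, but only 7 of 17 fbxc genes (adjusted p = 0.328) and 9 of 36 fbxa genes, while 7 fbxa genes were higher (median 0.23). In the skr family 13 of 17 genes were lower (median -1.55), with 3 X-linked, and in the ceh homeobox family 13 of 23, with 6 X-linked. As 81.4% of all X-linked genes were lower, these members add to both counts. C-type lectin genes (clec) were higher in 11 of 22 cases (median 1.34). By 1-sided Fisher's exact tests with Benjamini-Hochberg adjustment over all families and both directions, the adjusted p was 4.55e-09 for nhr, 1.29e-05 for fbxb, 2.44e-05 for skr, 0.00237 for ceh and 1.29e-05 for clec.

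In XO whole worms the neuropeptide families were higher, with 31 of 31 flp genes (median 1.55) and 53 of 64 nlp genes. So were 82 of 121 clec genes and 11 of 12 scl genes (median 7.85). Lower families were fbxb, with 43 of 47 (median -3.31), and nspc, a family of nematode-specific peptides, with 11 of 11, all X-linked (-4.17). By the same test the adjusted p was 8.61e-16 for flp, 3.38e-17 for nlp, 5.94e-17 for clec and 1.73e-20 for fbxb.

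Some genes first transcribed in early embryos were lower in XO gonads. The sdz family (transcripts that depend on SKN-1 in the embryo) and tbx-38 were noticed first, and a list of such genes was then written. The genes that prompted it make up 11 of its 18 tested members and 10 of its 13 falls, so they test nothing about the class. Of the 7 other members 3 fell, ceh-51 (-5.06), tbx-37 (-3.88) and vet-6 (-2.87). In XO gonads ceh-51 was at 0.0254 ± 0.0439 CPM and tbx-37 at 0.0731 ± 0.0763. In XX gonads they were at 1.04 ± 0.195 and 1.12 ± 0.0358, so the sizes of these 2 falls are poorly determined. The members vet-1, vet-2, pes-10 and pes-1 did not pass, and the median of the 7 was -0.97. Camera's p for these 7 was 0.014, and 0.147 with an estimated correlation. In whole worms 24 of 26 list members were lower in XO, including 6 of the 7 that had not prompted the list. By fitted value, 14 of 17 list members were lower in XX gonads than in XX whole worms, as for tbx-38 (-1.47) and vet-6 (-1.64). Whether XX oocytes transcribed embryonic genes therefore stays open, and older oocytes among the XX samples were not tested as a source.

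For X-linked genes in XO whole worms, the germline's share of the transcripts was examined as a source of the fall, and the values did not decide. Over all genes the difference from autosomal genes was -0.19. Among genes at least 8-fold lower in XX gonads than in XX worms, 711 X-linked and 2532 autosomal genes still differed by -0.18. The first bound used was already met by the value over all genes, so meeting it says nothing about the germline. By the log2 ratio of XX gonads to XX worms, the difference was -0.18 up to -5, -0.27 from -5 to -3, -0.40 from -3 to -1, -0.76 from -1 to 0 and -1.82 from 0 to 1 (236 X-linked genes), but -0.54 above 1 (24 X-linked genes).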
